A study of Homo sapiens with 6 samples.

How the data were processed

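Samples of MDA-MB-231 cells were compared in 2 groups, migratory and unsorted, with 3 samples each of 1000 cells. Per the labels' protocols, RNA was isolated with a low-input column kit, cDNA was amplified with a SMART-seq ultra-low-input kit, libraries were made by Nextera XT tagmentation and sequenced paired-end, each sample on 4 lanes. This chemistry does not mark the strand and carries no molecular identifiers, so amplified reads are not independent molecules, and the floors below cover counting error only. The labels do not say that the samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. They also do not say how long the unsorted cells spent in the device, so any effect of the device on the migratory cells goes with the group.

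The deposited values are a signal in read counts per gene divided by 1 size factor per sample, with no scaling for gene length. Per the submitters' processing notes, HISAT2, HTSeq and DESeq2 were used with the builds hg38 and GRCh38.p7. Their versions, settings and roles, the gene annotation and the rule by which genes entered the table are not given in the sources used here. Each sample's values were whole multiples of what 1 read was worth there, and 100% of values came out whole within 0.01 read. The size factors implied by these steps differed by at most 0.222% from median-of-ratios factors computed on the recovered reads. The table held 16258 gene symbols, and the lowest mean over the 6 samples was 8.09. No column of sample values was left unused. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom of 49.2 to 164), so no pair was treated as a single library deposited more than once. Separate amplifications of one RNA could differ as much, so this does not show that the samples are distinct, which rests on the labels.

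The main test was limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, on log2 of the deposited value + 1. Fold changes on this scale understate those of low genes. Genes with a mean of at least 10 were tested, which left 15786 and removed 472. Adjusted p-values are Benjamini-Hochberg, two-sided, with a threshold of 0.05. Count tests on the recovered reads used edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 as alternatives, and 3 adjusted p-values that DESeq2 gave as NA were kept as such. A floor of 3 reads per library, in the units of the table, was used where a group had no read.

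Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01 and again with an estimated correlation. The fry test, which asks whether a list's genes move one way without comparing them with other genes, was an alternative. The 36 lists were fixed before the data were examined, as were the tests, the named-gene rule and the alternatives not said to be added later, and the 33 lists with at least 5 tested members were tested. They covered mesenchymal, epithelial, actin and myosin, integrin, matrix protease, RAS-ERK, PI3K-AKT, FOXO, G2/M, S phase, apoptosis promoter and inhibitor, YAP-TAZ, TGF-beta, NF-kB, interferon, immediate early, heat shock, unfolded protein, hypoxia, oxidative phosphorylation, mitochondrial-encoded, ribosomal protein, cholesterol, p53, ion channel, stem and motility, autophagy, non-coding RNA and histone genes. Markers of keratinocytes, fibroblasts, blood cells, endothelium and erythroid cells made up the rest. The preset correlation treats genes of a list as nearly independent, which makes its p-values too small where they move together.

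Genes were named by a rule. It took the 10 largest changes per direction among genes past the threshold with a mean of at least 50 and no overlap between groups, filled by the smallest p where fewer passed and then said not to pass. It also took up to 4 members per list with the smallest p, and fixed genes, VIM, CDH1, CD44 and MKI67 among them, whatever their value. Some genes and 1 gene list that entered the tests and the counts are not reported here. Coordinates come from the GENCODE annotation of GRCh38 given for this work, matched by symbol for 85.8% of genes. The submitters' annotation may differ, HN1L, HN1 and SOD2 were not matched to a single gene, and no coordinates were converted. Overlap of exons with other genes was computed from the same annotation, for matched genes only.

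On simulated counts with the real means, depths and dispersions, limma recovered 10% of 2-fold and 63% of 4-fold changes, with 76 calls of which 3 were false, among 15355 genes. In the same simulation over 15786 genes edgeR recovered 9% and 62%, with 73 calls of which 2 were false, and DESeq2 33% and 76%, with 142 calls of which 33 were false. Lists with no simulated change were called in 0 of 20 runs, with genes simulated as independent, which real genes are not. With the 28 G2/M genes raised by 0.5 on the log2 scale, that list was called in 100% of 20 runs at the preset correlation, with 1.15 lists called per run, and in 90% with an estimated correlation, with 0.9 lists per run. Alternatives changed the pseudocount, the filter, the scaling, the variance trend, sample weights, the replicate block, the tool, and the libraries used, leaving out each in turn. After the data were seen, thinning all libraries to the shallowest total and removing a trend with GC content and transcript length per library were added. The latter used the longest annotated transcript of each gene and had lengths for 86.7% of tested genes.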

Results

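Gene expression was measured in MDA-MB-231 cells, an established human cell line from a triple-negative breast cancer that grows with a spindle shape and migrates readily in culture. Cells were seeded in microfluidic devices, from which highly motile cells were isolated as the migratory group. The unsorted population was the comparison group. Each group had 3 samples of 1000 cells, and RNA was amplified as full-length cDNA before paired-end sequencing. The deposited table held normalised read counts for 16258 genes. The reads behind them came to 32789072, 74227978 and 45860857 in the unsorted libraries and to 31276550, 27032454 and 34511537 in the migratory libraries. Values on a log scale correlated between libraries of one group at Pearson's r of 0.941 to 0.945 (unsorted) and 0.932 to 0.946 (migratory), and between groups at 0.914 to 0.939, across genes, which are not independent replicates. The first principal component held 33.7% of the variance and placed the 3 migratory libraries on the other side from the 3 unsorted ones. The second held 22.5% and set migratory replicate 1 apart from migratory replicates 2 and 3. It split the unsorted group too, with unsorted replicate 2 on the side of migratory replicates 2 and 3. Unsorted replicates 1 and 3 lay on the side of migratory replicate 1.

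The comparison asked which genes differ between highly motile cells and the population they came from. In the migratory cells 7 genes rose and 30 fell. FGF5, a fibroblast growth factor (chromosome 4, 80266599 to 80336680), rose from 227 ± 17.9 to 947 ± 60.6 normalised read counts (mean ± SD, n = 3 per group), a 4.16-fold change with a limma adjusted p of 0.018. HMOX1, the haem-degrading enzyme haem oxygenase 1 (chromosome 22, 35380361 to 35394214), rose from 2106 ± 513 to 7063 ± 863 with a limma adjusted p of 0.022. GCLM, the modifier subunit of the enzyme that limits glutathione synthesis, rose by a log2 fold change of 0.99 (SE 0.16). Other higher calls were HN1L at a log2 fold change of 1.59, RAD23B, a DNA repair factor that binds ubiquitin, at 1.56, and CLIC4, a chloride intracellular channel protein, at 1.20.

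Among the genes that fell, FOS, a subunit of the AP-1 transcription factor (chromosome 14, 75278774 to 75282230), went from 3700 ± 851 to 582 ± 41.7 normalised read counts (n = 3 per group), with a limma adjusted p of 0.0058. LGALS12, a galectin (chromosome 11, 63506084 to 63516774), fell from 1641 ± 565 to 169 ± 50.4 with a limma adjusted p of 0.0098. SERPINA5, the protein C inhibitor (chromosome 14, 94561442 to 94593120), was at 124 ± 70.6 in unsorted cells and had no read in any of the 3 migratory libraries, which makes it at least 32.6-fold lower against a floor of 3 reads per library. The secreted protease inhibitor SLPI fell from 233 ± 67.7 to 14.1 ± 10.5, and the actin-binding protein NEBL from 193 ± 62.5 to 22.1 ± 4.48. ID2, an inhibitor of basic helix-loop-helix factors, had a log2 fold change of -2.71, the water channel AQP5 of -2.65 and the collagenase MMP13 of -2.52. That of PI16 was -2.42 and that of the somatostatin receptor SSTR2 -2.35.

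**Figure D1:**
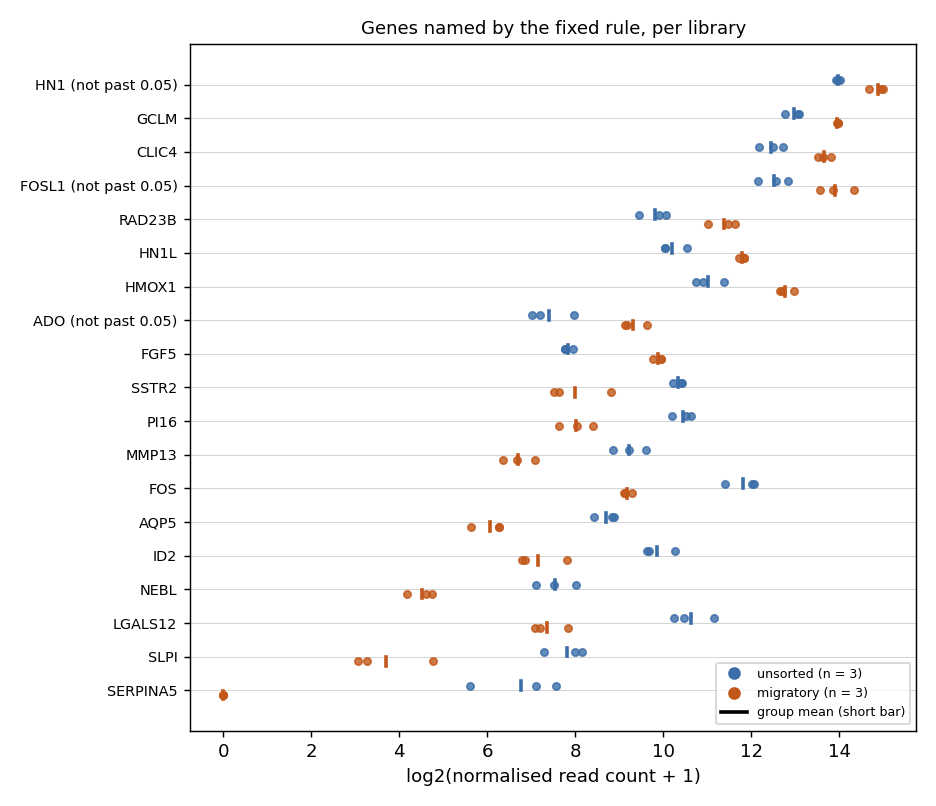
Normalised read counts of 19 genes on a log2 scale (x axis, log2 of the value + 1) in the 3 unsorted (blue) and 3 migratory (orange) libraries, with 1 point per library and a short bar at each group mean. The groups do not overlap for any of these genes, which the naming rule demanded; HN1, ADO and FOSL1 missed an adjusted p of 0.05.

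In all, 37 of 15786 tested genes passed an adjusted p of 0.05 in limma, 7 higher and 30 lower in migratory cells, and the groups did not overlap for any of the 37. At an unadjusted p under 0.05 there were 2796 genes, 1215 higher and 1581 lower. Values of the 2 groups did not overlap for 3750 genes, or 23.8% of those tested, where chance gives 10%. HN1, ADO and FOSL1 were the next genes by p among the higher ones and did not pass, with limma adjusted p of 0.0501, 0.054 and 0.054. FOSL1, another AP-1 subunit, was at 5968 ± 1348 in unsorted and 15862 ± 4418 in migratory cells. The remaining lower calls, named after their values were seen where no list holds them, were ID1, ICAM1, CXCL1, IFIT1, MT-CO1, TNFSF10, RARRES3, GGT1, P3H4, LOXL4, SCNN1A, ACSS1, CPE, PAQR8, PTGES, CEBPD, ISYNA1, ANGPTL2, MAGED1 and MAP2K6. TNFSF10, which encodes the death ligand TRAIL, fell from 16945 ± 6193 to 3264 ± 763. MAP2K6, a kinase that activates p38, was at 96.4 ± 11.9 in unsorted cells and had no read in the 3 migratory libraries, at least 25.3-fold lower against the same floor.

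The number of calls rested on the tool and on single libraries. The quasi-likelihood test of edgeR on whole reads called 21 genes, all among the 37, and DESeq2 called 933, which included all 37 in the same direction. Without unsorted replicate 1 or 3 limma called 1 gene, and without unsorted replicate 2 it called 2, FOS among them. It called 15 genes without migratory replicate 2 and 14 without migratory replicate 3. Exons of VIM, ELF3, TPM4, IFIT2, GGT1, SCNN1A, ISYNA1, CDH1 and PMEPA1 overlap another gene over 5.33% to 12.4% of their length. That range counts the largest single overlap of each gene, and the overlaps leave their values less certain.

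Of 23 measured NF-kB and inflammatory genes, 21 had lower values, 2 fell past the test over all genes and 12 passed when adjusted over the list alone. The adhesion receptor ICAM1 fell from 6706 ± 600 to 2057 ± 501 and the chemokine CXCL1 from 1048 ± 346 to 209 ± 62.9 normalised read counts. CCL2 was at 521 ± 316 in unsorted and 88.0 ± 31.0 in migratory cells, and SOD2 at 7934 ± 5084 and 2131 ± 609, without passing over all genes. The list median was -0.88 on the log2 scale, with a camera adjusted p of 1.3e-07 at a preset correlation and an adjusted p = 0.17 with an estimated correlation. Part of ICAM1's exon sequence, 22.0%, overlaps an antisense gene, and reads of the opposite strands cannot be told apart in these libraries.

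Interferon-stimulated genes had lower values for 21 of 23 measured members, with a median of -0.61. IFIT1, an antiviral RNA-binding protein, fell from 9072 ± 2982 to 2958 ± 486, and 8 members passed when adjusted over the list alone. IFIT2 was at 7615 ± 4125 in unsorted and 1935 ± 762 in migratory cells, and OAS1 at 426 ± 177 and 84.5 ± 52.3, without passing over all genes. The camera adjusted p was 6.6e-06, and the adjusted p = 0.18 with an estimated correlation.

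Among 21 immediate early genes, 15 had lower values and FOS fell, while FOSL1 had the higher value given above. FOSB was at 77.3 ± 21.2 in unsorted and 16.4 ± 5.91 in migratory cells. Adjusted over the list alone, 2 were lower and 1 was higher. The median was -0.57, with a camera adjusted p of 0.024 and an adjusted p = 0.59 with an estimated correlation. The call was lost without unsorted replicate 3 (adjusted p of 0.11), migratory replicate 1 (0.16, with a median of -0.26) or migratory replicate 2 (0.079). The call was barely kept without unsorted replicate 2 (median -0.36, adjusted p of 0.0498) and with array weights (-0.29, 0.0475). With a GC and length trend removed the median was -0.29 and the adjusted p 0.25.

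Of 28 genes of the G2/M phase and mitosis, 27 had higher values, with a median of 0.43 and a camera adjusted p of 7.0e-08 (adjusted p = 0.18 with an estimated correlation). None passed over all genes, and 5 did when adjusted over the list alone. TPX2, a spindle assembly factor, was at 8565 ± 199 in unsorted and 15410 ± 1419 in migratory cells, and the proliferation marker MKI67 at 2464 ± 366 and 4411 ± 429. BIRC5 was at 5553 ± 50.5 and 9036 ± 143. Genes of S phase were not called with all libraries (median 0.22, camera adjusted p of 0.10 for 28 genes), which does not show that they differ from the G2/M genes. They were called as higher without unsorted replicate 2 (adjusted p of 0.0062), without migratory replicate 1 (0.013) and with array weights (0.0064), and their median was 0.05 without unsorted replicate 3, 0.05 without migratory replicate 3, 0.08 without migratory replicate 2 and 0.10 without unsorted replicate 1.

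Actin and myosin genes had a median of 0.25 over 23 members (camera adjusted p of 0.0034), with 5 higher when adjusted over the list alone, and an adjusted p = 0.18 with an estimated correlation. The tropomyosin gene TPM3 was at 18718 ± 2262 and 35806 ± 6142, and TPM4 at 22084 ± 2202 and 36374 ± 4527. Stem and motility markers had a median of 0.16 over 20 members (camera adjusted p of 0.0055), and 4 passed when adjusted over the list alone. The adjusted p = 0.18 with an estimated correlation, and the median was 0.09 under upper-quartile scaling. MET, a receptor for hepatocyte growth factor, was at 3064 ± 846 and 5876 ± 330. YAP-TAZ targets had a median of 0.35 over 25 members (camera adjusted p of 0.0042, adjusted p = 0.41 with an estimated correlation). That median was 0.19 without unsorted replicate 1 or without migratory replicate 2, with the call kept, and 3 members passed when adjusted over the list alone. Library means of the YAP-TAZ list overlapped between groups, with unsorted replicate 2 at 0.276 and migratory replicate 1 at 0.095 from the unsorted mean. F3, the coagulation starter tissue factor, was at 21472 ± 3584 and 40803 ± 6693. No member of these 3 lists passed over all genes.

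Integrin and focal adhesion genes had a median of 0.33 over 26 members, with a camera adjusted p of 0.024 and an adjusted p = 0.59 with an estimated correlation. LIMS1, an adaptor at focal adhesions, was at 734 ± 114 and 1642 ± 320 and was the 1 member that passed when adjusted over the list alone. The call was lost without unsorted replicate 1 (adjusted p of 0.063), unsorted replicate 3 (0.16), migratory replicate 2 (0.25, median 0.17) or migratory replicate 3 (0.082). It was also lost with a filter at a mean of 50 (0.081) and with a GC and length trend removed (0.053, median 0.17). PI3K-AKT pathway components had a median of 0.35 over 20 members, with a camera adjusted p of 0.028 and an adjusted p = 0.51 with an estimated correlation. None of them passed, over all genes or when adjusted over the list alone. The call was lost without unsorted replicate 3 (0.17, median 0.17), migratory replicate 2 (0.14) or migratory replicate 3 (0.063). It was also lost with the filter at 50 (0.072) and with the GC and length trend removed (0.10, median 0.14).

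Ribosomal protein genes had higher values for 75 of 77 measured members, with a median of 0.42 and a camera adjusted p of 1.5e-14. None passed, over all genes or when adjusted over the list alone, and the adjusted p = 0.53 with an estimated correlation. RPL8 was at 19854 ± 1765 in unsorted and 32099 ± 8388 in migratory cells. The mean of the list lay 0.78 above the unsorted mean in migratory replicate 1 and 0.18 and 0.31 above it in the other two. Without migratory replicate 1 the list median was 0.25, and with array weights it was 0.27. Many of these genes have processed pseudogenes, and how reads shared with them were counted is not given in the sources used here. Heat shock genes had a median of 0.40 over 13 members (camera adjusted p of 3.6e-04, adjusted p = 0.46 with an estimated correlation), and 0.21 without migratory replicate 3. HSP90AA1, a cytosolic chaperone, was at 57323 ± 6563 and 87307 ± 13219, and 3 members passed when adjusted over the list alone, none over all genes. Genes of the unfolded protein and amino acid response had a median of 0.39 over 24 members (camera adjusted p of 0.0063, adjusted p = 0.53 with an estimated correlation). Without migratory replicate 3 the median was 0.11 and the adjusted p 0.18. PSAT1, a serine synthesis enzyme, was at 3065 ± 481 and 6600 ± 2379. Adjusted over the list alone, 6 members were higher and 1 was lower, and none passed over all genes.

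Epithelial genes had lower values for 15 of 17 measured members (median -0.38, camera adjusted p of 0.0042, adjusted p = 0.28 with an estimated correlation). The transcription factor ELF3, at 291 ± 127 in unsorted and 35.4 ± 20.1 in migratory cells, was the 1 member that passed when adjusted over the list alone, and none passed over all genes. Without migratory replicate 1 the median was -0.23, with the call kept. KRT19 was at 47127 ± 9783 and 30989 ± 5706. Hypoxia and glycolysis genes had lower values for 22 of 30 members (median -0.28, camera adjusted p of 0.0055, adjusted p = 0.22 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase, was at 2042 ± 163 and 1068 ± 41.1, and 5 members passed when adjusted over the list alone, none over all genes. Of 15 mitochondrial-encoded transcripts 14 had lower values (median -0.31, camera adjusted p of 0.0045, adjusted p = 0.59 with an estimated correlation). MT-CO1, cytochrome c oxidase subunit 1, fell from 102978 ± 27171 to 38919 ± 7117 and also passed over the list alone. Mitochondrial transcripts took 2.17%, 1.66% and 1.37% of reads in the unsorted and 1.57%, 0.951% and 1.12% in the migratory libraries. The mitochondrial call was lost without unsorted replicate 1 (0.11, median -0.16) or migratory replicate 2 (0.22, median -0.15). The median was -0.49 without unsorted replicate 3, and -0.51 without migratory replicate 1 or with the GC and length trend removed.

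Markers of other cell types were examined for signal from cells outside the line. A cell line can express such genes itself, so their values do not show that other cells were present or were lost on sorting. All 7 measured fibroblast markers had lower values in migratory cells (median -0.91, camera adjusted p of 0.0051, adjusted p = 0.18 with an estimated correlation). COL1A2 was at 1956 ± 818 and 641 ± 399, and 2 members passed when adjusted over the list alone, none over all genes. Endothelial markers were not called (median -1.01 over 7 members, camera adjusted p of 0.25), and their median was -0.25 without migratory replicate 2, -0.50 without migratory replicate 1 and -0.56 with a GC and length trend removed. PECAM1 was at 1565 ± 316 and 783 ± 197. Of the keratinocyte list 4 genes were measured and of the haematopoietic list 2, too few for the test, and no erythroid gene was in the tested set. KRT10 was at 4983 ± 918 and 5406 ± 1461, and CD14 at 356 ± 66.1 and 65.6 ± 41.1, with a limma adjusted p of 0.069 for CD14.

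**Figure D2:**
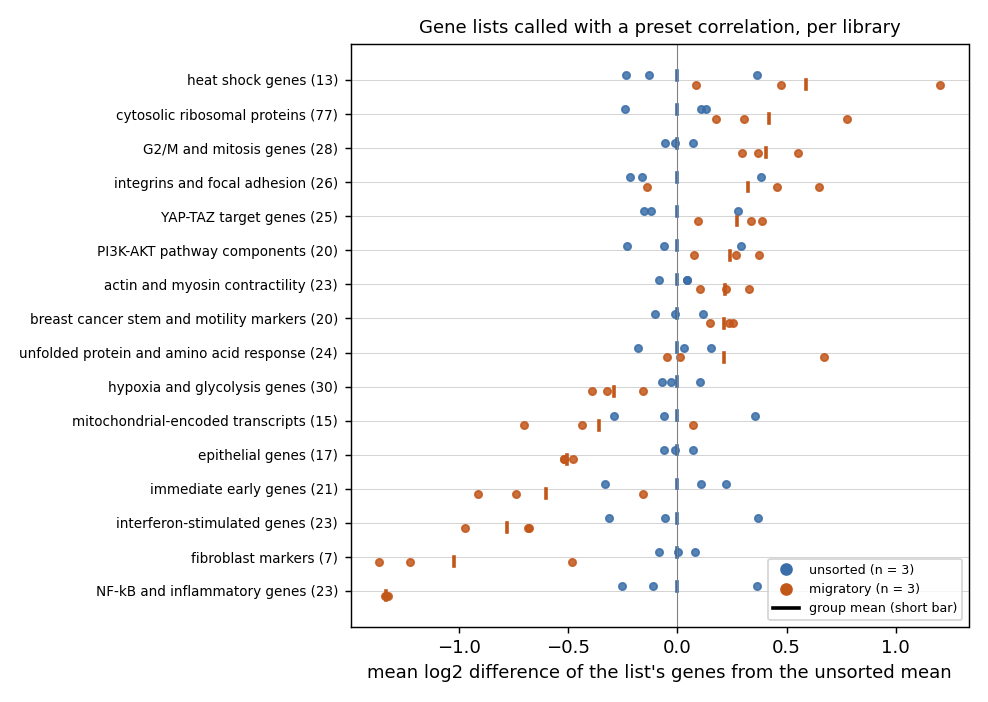
Mean log2 difference from the unsorted mean (x axis) over the genes of 16 called lists, with 1 point per library, unsorted in blue and migratory in orange, a short bar at each group mean and the number of measured genes in parentheses. The library means of the groups do not overlap for 9 of the lists and overlap for the other 7, heat shock, integrin and YAP-TAZ genes among them.

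The mesenchymal list was not called (median -0.54 over 19 members, camera adjusted p of 0.37), and its members went both ways. Its median was -0.32 without unsorted replicate 1 or migratory replicate 1, and down to -0.73 with another library left out. The transcription factor SNAI1 was at 530 ± 296 in unsorted and 124 ± 19.97 in migratory cells, and the receptor tyrosine kinase AXL at 13426 ± 648 and 21313 ± 4758. TGF-beta targets were likewise mixed (median -0.40 over 18 members, camera adjusted p of 0.32), and ID1 and ID2 fell. PMEPA1 had the higher value in migratory cells, at 1458 ± 197 and 3389 ± 692, without passing over all genes. Adjusted over the list alone, 2 members were higher and 3 lower. The list median was -0.62 without unsorted replicate 1, -0.24 without unsorted replicate 2, -0.21 without migratory replicate 1 and -0.25 with array weights. ID1 went from 6954 ± 327 to 1746 ± 710. Among 19 matrix proteases and inhibitors (median -0.09, camera adjusted p of 0.15) MMP13 fell, and the list was called as lower without unsorted replicate 1 (adjusted p of 0.035, median -0.15). Its median was -0.04 without unsorted replicate 3 (adjusted p of 0.25), -0.15 without migratory replicate 3, -0.16 with upper-quartile factors and -0.18 with a GC and length trend removed, all without a call. Among 22 ion channel and volume genes (median -0.06, camera adjusted p of 0.96) CLIC4 rose and AQP5 fell. The direction of the ion channel list's camera test changed with the setting.

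Lists without a call in the full data and without a member past the test over all genes were histones (median -0.32, camera adjusted p of 0.056), RAS-ERK targets (0.23, 0.058), FOXO targets (-0.23, 0.19) and autophagy and lysosome genes (-0.15, 0.26). The same held for apoptosis inhibitors (0.09, 0.28), nuclear oxidative phosphorylation genes (0.09, 0.35), cholesterol synthesis genes (0.14, 0.37) and apoptosis promoters (0.08, 0.67), whose mean was -0.05. It also held for nuclear non-coding RNA (0.07, 0.87) and p53 targets (-0.03, 0.94), where the direction of the test for oxidative phosphorylation, non-coding RNA and p53 lists changed with the setting. Some of these lists were called under other settings. RAS-ERK targets were called as higher without unsorted replicate 2 (0.034), unsorted replicate 3 (0.022) or migratory replicate 1 (0.0052, median 0.39), with array weights (0.020, median 0.36), with a GC and length trend removed (0.039) and under 1 further setting. Their median was 0.10 without unsorted replicate 1 or migratory replicate 2 and 0.09 without migratory replicate 3. FOXO targets were called as lower without unsorted replicate 1 (0.020, median -0.56), and their median was -0.14 without migratory replicate 1. Histones were called as lower without unsorted replicate 2 (0.0093) or migratory replicate 1 (0.036), with array weights (0.013), a filter at a mean of 50 (0.024, median -0.52), thinning (0.0498), the GC and length trend removed (0.033) and under 1 further setting. Members of the histone list went both ways, with 11 lower and 4 higher values. Adjusted over the list alone, 4 histone genes were lower and 1, HIST1H4C, was higher. Oxidative phosphorylation genes were called as higher without migratory replicate 2 (0.0050, median 0.28). Without a call, leaving out 1 library gave medians of -0.04 to 0.19 for apoptosis inhibitors, -0.03 to 0.14 for apoptosis promoters, 0.03 to 0.21 for cholesterol synthesis and -0.19 to -0.09 for autophagy and lysosome genes. The median of the apoptosis inhibitors was -0.03 with the GC and length trend removed, so no direction is given for either apoptosis list. The following genes fixed in advance did not pass in limma. VIM was at 14465 ± 1241 and 18533 ± 1560 (limma adjusted p of 0.26), CD44 at 20267 ± 1352 and 23109 ± 1231 (0.51) and MKI67 as given above (0.098). CDH1, at 13.2 ± 14.3 and 8.90 ± 10.5, was near the lower limit of the table, where a difference was not detectable at this depth.

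Camera called 17 of 33 tested lists at a preset correlation of 0.01, 10 higher and 7 lower, and 0 with an estimated correlation, where the lowest adjusted p was 0.17. Other ways of splitting the 6 libraries into 3 and 3 gave up to 13 called lists at the preset correlation with the real split at 17.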

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

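Thinning and the removal of a GC and length trend were chosen after the data were seen; all other alternatives were planned. The 37 calls kept their direction under each alternative in which they were tested, but their number moved widely. The count of called genes, with higher and lower ones, was 68 (12 and 56) at a pseudocount of 5, 78 (17 and 61) with a filter at a mean of 50, 104 (10 and 94) with upper-quartile factors, 507 (198 and 309) with array weights, 21 (4 and 17) with edgeR, 933 (364 and 569) with DESeq2 and 162 (72 and 90) with the GC and length trend removed. At a pseudocount of 0.5 only 4 were higher. The higher share was 18.9% in the reported result, 39.0% with DESeq2, 39.1% with array weights and 44.4% with the GC and length trend removed. Without a variance trend 48 genes were called, of which 9 are shared with the 37. Leaving out 1 library gave 1 to 44 calls (1 to 5 higher, 0 to 39 lower). With the same number of samples, 44 genes were called without migratory replicate 1 and 1 without unsorted replicate 1. Fewer samples may be part of the cause, but neither that nor the causes of the other shifts were tested. In the self-test DESeq2 made 33 false calls of 142.

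With a replicate block 114 genes were called (24 higher, 90 lower), and the RAS-ERK (adjusted p of 0.026) and histone lists (0.048) gained a call. Deviations of same-numbered samples correlated at 0.117, 0.108 and 0.0369, and those of differently numbered samples at -0.162 to 0.0723. Unsorted replicate 3 correlated best with migratory replicate 1 (0.0481). The labels do not say whether the numbers pair the samples, and these values leave it open, so the main test was unpaired.

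The 17 list calls ranged from 14 to 20 over the alternatives, except 0 with an estimated correlation and 2 with fry (the NF-kB list among them), whose question differs. For 4 lists without a call the direction of the camera test changed, which can differ from the sign of the median, and for KRT10 and CDH1 the sign of the fold change did; the cause was not tested. With array weights the median was -0.071 for oxidative phosphorylation, 0.13 for p53, 0.14 for ion channels and -0.088 for non-coding RNA, and KRT10 was at -0.0940. With the GC and length trend removed it was 0.12 for p53, -0.071 for ion channels and 0.14 for non-coding RNA, and with upper-quartile factors -0.12 for ion channels. Leaving out 1 library gave medians of -0.10 to 0.28 for oxidative phosphorylation, -0.25 to 0.18 for p53, -0.24 to 0.23 for ion channels and -0.13 to 0.23 for non-coding RNA, and fold changes of -0.080 to 0.33 for KRT10 and -1.83 to 0.80 for CDH1. Upper-quartile factors moved the median of all genes from -0.03 to -0.09. Depth limits genes with no read in a group to a lower bound on the fold. At similar depth 237 genes had no read in unsorted replicate 1 (32789072 reads) and 509 in migratory replicate 3 (34511537 reads), so depth alone does not set that number.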

Other observations

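The tests of the ribosomal GC and length trend, of migratory replicate 1 and of heat shock genes were chosen only after the results were seen, and so was the condition in both of the latter that a value must exceed the spread between libraries. Without that condition the values of both tests would have counted against their explanation. The MHC class I and NRF2 lists were also made only after the results were seen.

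Several genes had no read in any migratory library. There were 33 such genes with reads in all 3 unsorted libraries, against 3 with reads in all 3 migratory and none in unsorted libraries. Besides SERPINA5 and MAP2K6, and named after their values were seen, they included IDO1, the tryptophan-degrading enzyme, at a mean of 66.1 normalised read counts and at least 17.4-fold lower, the cadherin CDH16 at 58.9 and at least 15.5-fold lower, and the peptide gene NTS at 56.7 and at least 14.9-fold lower, against a floor of 3 reads per library. In the reverse direction CCIN was at 43.2 and the cation channel TRPM2 at 31.1 in migratory cells, at least 17.7-fold and 12.7-fold higher. Of the genes named in this paragraph, only SERPINA5 and MAP2K6 passed the limma test over all genes. Genes of low abundance were lower in migratory cells as a whole, as given below. The 33 against 3 was not separated from that shift.

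A hypothesis that antigen presentation genes may follow the interferon-stimulated genes was tested on a separate list. All 11 measured MHC class I antigen presentation genes, of 18 listed, had lower values in migratory cells (median -0.37), with a camera p of 0.0048 at the preset correlation and 0.055 with an estimated one. HLA-C was at 498 in unsorted and 279 in migratory cells and B2M at 16451 and 12494, and no member passed over all genes or when adjusted over the list alone. A second hypothesis was that HMOX1 and GCLM could be part of a broader rise of NRF2 targets. The other 25 targets gave a camera p of 0.50 with a median of 0.08, with 14 higher and 11 lower in value. Adjusted over the list alone, 4 were higher and 3 lower, and none passed over all genes. No common rise was seen, but camera asks only for a common shift, so a rise of part of the targets was left undecided. NQO1 was at 14969 and 24941 and TXNRD1 at 14817 and 24960, while the glutathione peroxidase GPX2 was at 152 and 1.90.

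Genes of low abundance were lower in migratory cells. The median log2 fold change was -0.45 over 1808 genes with a mean of 20 to 50, and 0.11 over 2919 genes above 3000. Lower read depth is argued against as the cause, since thinning all libraries to 27032454 reads left a median of -0.433 (10 draws, -0.442 to -0.422). Random loss of molecules would leave the summed value unchanged, but the log2 ratio of summed values was -0.388, with each migratory library below each unsorted one. A DNA background in the unsorted libraries stays open. Spearman's correlation with the length of the longest annotated transcript was -0.103 across 1226 genes (95% bootstrap interval over genes of -0.159 to -0.0536). That narrowly met the limit set in advance for this explanation, with an interval that reached to both sides of the limit. Only 67.8% of the genes had a length, so the check was not taken to decide. That condition on coverage was not part of the prediction. Rare cell states lost on sorting were not tested.

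The higher ribosomal protein genes kept a list median of 0.442 when the GC and length trend was removed. That argues only against a trend with the GC content and length of each gene's longest annotated transcript as the whole cause. The transcript expressed may be shorter, so a trend with its length was not excluded. Without migratory replicate 1 the median was 0.251, below 2 SD (0.418) of the list means of unsorted libraries. That SD describes single libraries and not a difference between groups. The list means of migratory replicates 2 and 3 (0.178 and 0.307) lay above those of unsorted replicates 1 to 3 (0.108, -0.241 and 0.133). A contribution of migratory replicate 1 alone cannot be told apart from a difference of the group with 3 libraries. A biological difference between migratory and unsorted cells stays open, untested, as does the time in the device.

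The lower NF-kB and interferon-stimulated genes are not accounted for by the shift of low-abundance genes. None of 10000 random lists matched on mean value had a median as low as the -0.80 of both lists together. The median of such random lists was typically 0.000337. The random-list p was 1e-04, the smallest these draws can give. It draws genes as if independent, and both lists were chosen because they were low in these data. It therefore bears on abundance only, not on whether the lists differ. For that, camera with an estimated correlation gave adjusted p of 0.17 (NF-kB) and 0.18 (interferon). A handling stress that raises immediate early and heat shock genes together in unsorted cells may contribute. Heat shock genes had a median of at least 0.207 in the other direction with each library left out, but their library means overlapped between groups, so this stays open. So do, untested, the time in the device and a difference of the migratory cells themselves.

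With 3 against 3 samples there are 10 splits, too few for a share under 0.05. The real split gave 37 genes and the highest other 0, and for gene lists 17 and 13.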
